A study of Mus musculus with 23 samples.

How the data were processed

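Gene expression was measured in the cortex of mice on 23 Illumina Sentrix BeadChip arrays, 1 per sample, each with 46235 probes. Per the labels' protocols, total RNA was isolated from dissected cortex, treated with DNase, amplified to biotin-labelled cRNA and hybridised. The deposited table holds the authors' log2 intensity of each probe on each array. The scale was read from the values, which lie between 5.45 and 15.7 and have quartiles of 6.18, 6.48 and 7.83 on all arrays, with a largest spread of the quartiles between arrays of 7.84e-05. The authors had therefore brought all arrays to the same distribution, as quantile normalization does. The background correction and the normalization method are not given in the sources used here, and limma is named without a role per the submitters' processing notes. Detection p-values, scan dates and slide positions were not used here, so a dim probe cannot be told from background and no batch could be entered in a model. Signal near the lower quartile is compressed towards the background, which makes fold changes of dim probes too small. A distribution forced to be identical also sets the changes of all probes on an array relative to each other.

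Arrays were grouped by the genotype and treatment in the labels. Replicate numbers were given in accession order and only name a sample. Wild-type untreated arrays 2 and 6 carry titles that differ by a letter and might be from the same mouse. A rule fixed in advance averaged them if their deviations from the group mean correlated more than those of every other pair of arrays within a group. Their r was 0.599, the highest of the 55 pairs within groups, against a highest value of 0.416 and a median of 0.199 among the other pairs. They were therefore counted as 1 sample, named wild-type untreated mouse 2, which left 22 samples. The correlation is across probes, which are not independent replicates. The labels do not say in so many words that each other array is a different mouse, and p-values measure the spread between these samples.

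Probes were named through the platform's annotation table, in which 35784 probes had 1 gene symbol, 0 had several and 10451 were not listed and are unnamed here. Of the symbols, 3274 were updated through the gene table of the reference assembly GRCm38.p6, which was used only for names and for the order of genes along chromosomes. Probes above their array's median on at least 5 arrays were kept, which left 25826, and the brightest kept probe stood for each gene. The 17951 features tested comprised 13562 with a gene symbol and 4389 unnamed probes. Values were used as deposited, without a pseudocount. One limma model (lmFit and eBayes, limma 3.58.1 in R 4.3.3) with a mean for each of the 4 groups was fitted to all 22 samples, and 5 contrasts were tested with two-sided tests: the genotype effect without and with DO1, the DO1 effect in each genotype, and the difference of the DO1 effects. P-values were adjusted by the Benjamini-Hochberg method over all features, with a threshold of 0.05. Changes are given in log2 with the standard error of the model.

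Gene lists, 37 in all with 697 entries of which 646 were on the array, were fixed before the data were examined. They cover microglia, astrocytes, oligodendrocytes, neurons of several kinds, vessels, blood, meninges, choroid plexus, neighbouring brain regions, inflammation, lysosomes, amyloid processing, metabolism, stress responses, the clock, immediate early genes, sex chromosome genes, housekeeping genes and the transgene and promoter genes. A list's score in a sample is the mean log2 value of its tested members. Scores were compared between groups by exact two-sided permutation of all splits of the samples, and for the difference of the DO1 effects by 1e+05 random permutations of treatment within genotype, with Benjamini-Hochberg adjustment over the 37 lists within a comparison. The smallest p was 0.0079 for the genotype effect in untreated mice and 0.0022 for the other comparisons of groups. With these limits at least 6 lists in the former and 2 in the latter must reach the smallest p before any can pass. The limma function camera, with an estimated and with the preset correlation between genes, compared each list with all other genes.

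Genes named in the text follow a rule fixed together with the lists: the 10 largest rises and 10 largest falls past the threshold in each comparison, up to 4 members with the smallest p among those of each list that passed or the 1 member with the smallest p where none did, and App, Thy1 and Prnp always. Psen1 belongs to the last set but has no named probe here. Exceptions are marked where they occur.

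The model was tested on simulated data built on the 17951 features with 100 genes changed by a log2 value of 0.5 and 100 by 1. In the genotype effect in untreated mice it recovered 87 and 99 of them with 10 false calls, and in the DO1 effect in transgenic mice 91 and 97 with 10. The DO1 effect in wild-type mice gave 91 and 99 with 17, and the genotype effect in DO1-treated mice 90 and 95 with 15. The difference of the DO1 effects gave 58 and 98 with 5 false calls, so changes of 0.5 in that comparison were often missed. In the list test, 10 of 37 simulated lists were shifted by 0.3. All 10 passed in 4 comparisons and 9 in the DO1 effect in wild-type mice, and 1 unshifted list passed in the difference of the DO1 effects. The simulated members varied independently of each other, while members of a real list can vary together. The share of real shifts of this size that would be found is therefore not known from this.

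Alternatives covered the filter on dim probes, cyclic loess, subtraction of the 75th percentile, quantile normalization, other handling of a gene's probes and of the averaged arrays, trended and robust moderation, array weights, fits on the compared groups only, the first residual component as a covariate, other list summaries, and leaving out each sample in turn. A covariate for the sex of the mice, which the labels do not give, was not run because the samples did not split within groups on the sex chromosome genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.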

Results

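Cortical gene expression was profiled in mice aged 9.5 months on a B6SJL background. Transgenic 5xFAD mice, which carry mutant human APP and PSEN1 transgenes under the Thy1 promoter and develop amyloid plaques, were compared with wild-type mice. In each genotype some mice had eaten chow with DO1, a compound known here by its code name only, at 0.652 g per kg of food for 8 months from an age of 6 weeks, and the others were untreated. The 23 arrays comprised 6 wild-type untreated, 6 wild-type DO1, 5 transgenic untreated and 6 transgenic DO1 arrays. Averaging of a pair of wild-type untreated arrays that appeared to be from the same mouse left 5 wild-type untreated samples and 22 samples in all. The number of samples sets the precision, and all values are log2 intensities with the same distribution on every array. Sample titles are numbered in a separate block for each group, and no batch is given, so treatment cannot be told apart from a processing batch that follows it. Genotype is also numbered in blocks within each treatment, so a batch that follows these blocks cannot be told apart from it either. The genotype effects without and with DO1 were measured in different samples and are compared with each other at the end. Transgenic mice come before wild-type mice in the numbering of both treatments, so that comparison does not settle the matter.

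The first comparison asks how the transgenes changed the cortex of untreated mice. Among the transgene and promoter genes, Thy1 was higher in transgenic mice by 0.87 ± 0.08 (SE; limma adjusted p = 2.33e-08), a 1.82-fold difference from a mean of 14.5 ± 0.04 (SD, n = 5) to 15.3 ± 0.18 (SD, n = 5). App differed by −0.08 ± 0.05 (adjusted p = 0.297) and Prnp by −0.04 ± 0.05 (adjusted p = 0.706), and probes made for mouse transcripts need not detect human ones. The largest rises were in genes of activated microglia and astrocytes. Cst7, a cystatin of activated microglia, rose by 3.30 ± 0.15 (adjusted p = 3.49e-13). The chemokines Ccl4 and Ccl3 rose by 3.27 ± 0.15 and 3.14 ± 0.15. Wild-type means of Cst7, Ccl4 and Ccl3 were 6.46, 6.53 and 6.37, near the array median of 6.48 and not shown to be above background, so no fold is given for them. Rises were also found for the lysozymes Lyz2 and Lyz1, by 3.05 ± 0.14 and 2.87 ± 0.18. Gfap, the intermediate filament of reactive astrocytes, rose by 2.92 ± 0.12 and Serpina3n, a secreted protease inhibitor, by 2.98 ± 0.20. The microglial receptor Trem2 rose by 2.86 ± 0.19, its adaptor Tyrobp by 2.54 ± 0.16 and complement C4b by 2.43 ± 0.26. In all, 1952 of 17951 features passed the threshold, 1050 higher and 902 lower. The lower count was 590 without transgenic untreated mouse 2 and 552 with only the compared groups in the model. At least 1.5-fold changes were found in 266 of the higher and 29 of the lower ones.

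Of 30 tested genes of disease-associated microglia 24 rose and 0 fell, and the list score was higher by 1.30 ± 0.07 (SE; exact permutation test, adjusted p = 0.0184). This adjusted p is shared by every list at the smallest p the permutations allow. General microglia and macrophage genes were higher by 0.99 ± 0.09, with 21 of 23 risen, among them Cyba by 1.71 ± 0.10, Laptm5 by 1.79 ± 0.11, Cd14 by 1.90 ± 0.12 and Mpeg1 by 2.15 ± 0.14. Homeostatic microglia genes were also higher, by 0.63 ± 0.07 with 9 of 16 risen, including Cx3cr1 by 1.71 ± 0.15 and Csf1r by 0.99 ± 0.10. Complement genes were higher by 1.08 ± 0.13, with 6 of 10 risen, including C1qa by 1.79 ± 0.16. Lysosome genes were higher by 0.71 ± 0.03, with 14 of 24 risen, led by Cd68 at 2.31 ± 0.11 and the glycosidase Gusb at 1.72 ± 0.12. Reactive astrocyte genes were higher by 0.80 ± 0.07, with 12 of 21 risen, including the cytokine receptor Osmr by 1.54 ± 0.15. General astrocyte genes were higher by 0.18 ± 0.03, with 5 of 16 risen, and cytokine and chemokine genes by 0.41 ± 0.05, with 6 of 13 risen, including Cxcl16 by 1.13 ± 0.11 and Tgfb1 by 1.35 ± 0.14. These 8 lists also passed against all other genes with an estimated correlation, and in each of them all 5 transgenic samples lay above all 5 wild-type ones. When p-values were adjusted over the list alone, 26 disease-associated, 22 general and 11 homeostatic microglia genes were higher, with 7 complement, 15 lysosome, 14 reactive astrocyte, 6 general astrocyte and 6 cytokine genes. The same adjustment called 1 gene lower in each of the disease-associated microglia, complement, lysosome, general astrocyte and cytokine lists.

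A further 13 lists passed the permutation test but not the test with an estimated correlation. Their exact permutation adjusted p was 0.042 for cholesterol synthesis, 0.0294 for MHC class I, oligodendrocyte precursor, inhibitory neuron and striatum genes, and 0.0184 for the others. In each of the 13 lists all 5 transgenic samples lay beyond the wild-type mean. Genes of MHC class II and antigen presentation were higher by 0.50 ± 0.10, with 4 of 9 risen, including Cd86 by 1.16 ± 0.12 (list adjusted p = 0.153 with an estimated correlation). MHC class I genes were higher by 0.48 ± 0.12 (adjusted p = 0.242 with an estimated correlation), with 2 of 12 risen, H2-D1 by 1.24 ± 0.29 and Psmb8 by 0.98 ± 0.20. Interferon response genes were higher by 0.31 ± 0.06 (0.288 as the adjusted p with an estimated correlation), with 3 of 20 risen, and 8 when adjusted over the list alone. Amyloid processing and clearance genes were higher by 0.21 ± 0.05 (adjusted p = 0.0801 with an estimated correlation), with Trem2 and Apoe (0.86 ± 0.09) risen and the amyloid-degrading peptidase Mme fallen by 0.48 ± 0.09. With the mean of a gene's probes in place of the brightest, the call for Mme ended (limma adjusted p = 0.0529). Antioxidant and Nrf2 target genes were higher by 0.16 ± 0.04 (adjusted p = 0.0801 with an estimated correlation), with Hmox1 risen by 0.54 ± 0.13 and the metallothioneins Mt1 and Mt2 by 0.32 ± 0.06 and 0.50 ± 0.13, and 9 of 21 higher when adjusted over the list alone. The Mt2 call ended without wild-type untreated mouse 1 or transgenic untreated mouse 5, at adjusted p of up to 0.0601. Cholesterol synthesis genes were higher by 0.13 ± 0.05 and oligodendrocyte precursor genes by 0.10 ± 0.03 (adjusted p = 0.189 and 0.288 with an estimated correlation). Cholesterol synthesis lost the permutation call without wild-type untreated mouse 1, 3, 4 or 5 or transgenic untreated mouse 3, 4 or 5, at adjusted p from 0.0511 to 0.0839. The precursor list lost it without wild-type untreated mouse 1 or transgenic untreated mouse 1, 4 or 5, at adjusted p from 0.0511 to 0.0618. Housekeeping genes were higher by 0.14 ± 0.04 (adjusted p = 0.494 with an estimated correlation), through Gusb, which is also a lysosomal enzyme, and Actb (0.50 ± 0.09, but 0.25 with an adjusted p of 0.209 for the mean of its probes). The sex chromosome list was higher by 0.21 ± 0.07 through Xist alone, which rose by 0.84 ± 0.16, while the list's median was −0.03 (adjusted p = 0.655 with an estimated correlation). The transgene and promoter list was higher by 0.25 ± 0.04 through Thy1, with a median of −0.04 (adjusted p = 0.409 with an estimated correlation).

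The falls were smaller. Circadian clock genes were lower by −0.25 ± 0.07 (exact permutation test, adjusted p = 0.0184; 0.238 as the adjusted p with an estimated correlation), with Per2 fallen by 0.86 ± 0.20, Ciart by 0.62 ± 0.16 and Nr1d2 by 0.39 ± 0.10. In this list 5 of 14 fell and 1 rose, also when adjusted over the list alone. Without wild-type untreated mouse 1 or 5 the clock list had an adjusted p of 0.0587. Inhibitory neuron genes were lower by −0.13 ± 0.04 (adjusted p = 0.259 with an estimated correlation), with the neuropeptide Cort fallen by 1.30 ± 0.21 and the calcium-binding protein Pvalb by 0.40 ± 0.08. This list lost its permutation call without any of wild-type untreated mice 1 to 4 or transgenic untreated mouse 1, 2, 4 or 5, at adjusted p from 0.0511 to 0.0699. Striatum genes were lower by −0.17 ± 0.05, with 3 of 12 fallen (adjusted p = 0.189 with an estimated correlation). Activity-regulated immediate early genes had a score of −0.49 ± 0.19 that missed the threshold (exact permutation test, adjusted p = 0.0734, but 0.044 without wild-type untreated mouse 3 and 0.0383 without transgenic untreated mouse 3), with 4 of 16 fallen, among them Npas4 by 1.19 ± 0.20, Dusp1 by 0.96 ± 0.25 and Egr1 by 0.87 ± 0.24. Other large falls were those of Uap1, an enzyme of amino sugar synthesis, by 2.25 ± 0.52 (adjusted p = 0.00576), the T cell receptor segment Trbv13-2 by 1.15 ± 0.36, the neuropeptide Adcyap1 by 0.77 ± 0.11, the calcium channel Ryr1 by 0.75 ± 0.14 and Fosl2 by 0.75 ± 0.13. Uap1 lay at 2 separate levels across the mice, and its fall rests on 4 of 5 transgenic samples. The Egr1 call ended without wild-type untreated mouse 1 or 5 or transgenic untreated mouse 1, 2 or 5, at adjusted p from 0.0515 to 0.0707. That of Trbv13-2 ended without any of wild-type untreated mice 2 to 5 or transgenic untreated mice 1 to 4, at adjusted p from 0.0538 to 0.106.

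The remaining lists had scores that did not pass. They were oligodendrocyte and myelin genes at 0.12 ± 0.06, excitatory cortical neurons at 0.03 ± 0.03, deep-layer cortical neurons at −0.04 ± 0.03, synapse at 0.03 ± 0.03, oxidative phosphorylation at −0.03 ± 0.02, and heat shock and unfolded protein response at −0.09 ± 0.04. Glucocorticoid targets stood at 0.06 ± 0.05, endothelium at 0.02 ± 0.03, pericytes and smooth muscle at 0.05 ± 0.05, meninges and fibroblasts at −0.10 ± 0.04, choroid plexus at 0.02 ± 0.18, erythrocytes at 0.13 ± 0.25, lymphocytes and neutrophils at 0.12 ± 0.04, hippocampus at 0.08 ± 0.04, and thalamus and hypothalamus at −0.13 ± 0.15. Some passed without 1 sample in the permutation test. Without transgenic untreated mouse 3 these were hippocampus, heat shock and oligodendrocyte genes (adjusted p = 0.0383 each) and oxidative phosphorylation (0.047). Without transgenic untreated mouse 4 they were hippocampus and lymphocytes and neutrophils (0.044 each), the latter also without wild-type untreated mouse 1 (0.0489). Mean and median differed in sign for pericytes and smooth muscle, choroid plexus and hippocampus.

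**Figure D1:**
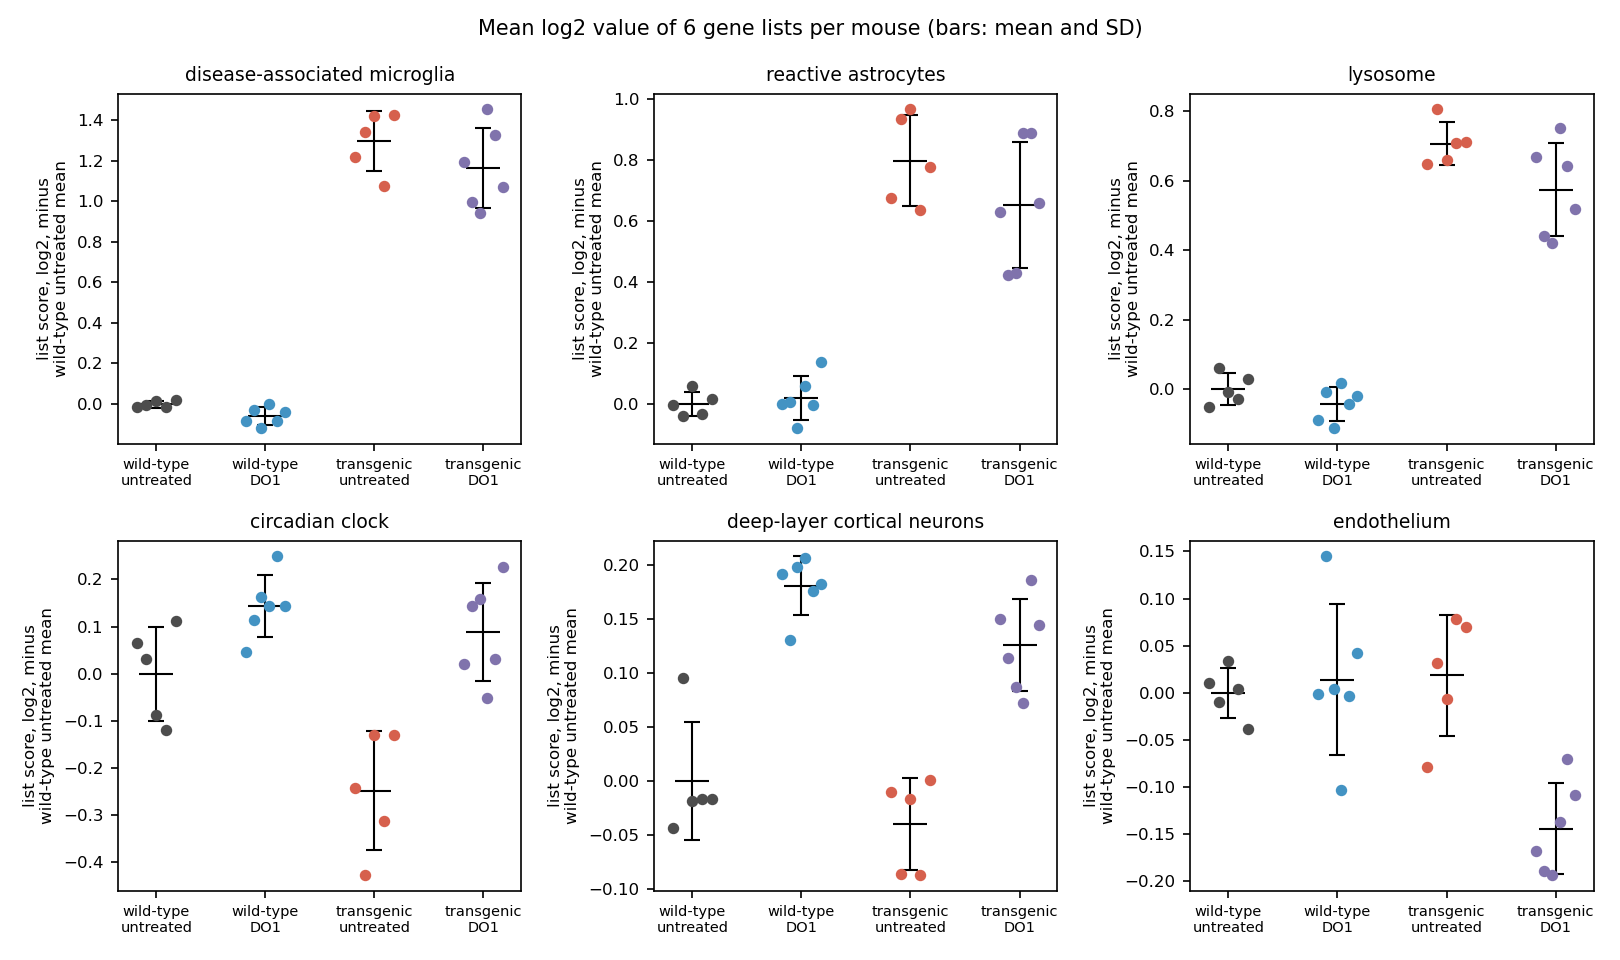
Score of 6 gene lists in each mouse (mean log2 value of the list's genes, minus the mean of the wild-type untreated mice), by group; points are samples, horizontal bars are means and vertical bars are SD, with n = 5, 6, 5 and 6. The microglia, astrocyte and lysosome lists lay higher in both transgenic groups, with disease-associated microglia higher by 1.30 without and 1.22 with DO1, and the clock list was lowest in untreated transgenic mice.

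The second comparison asks what DO1 changed in transgenic mice. In this group 2016 features passed the threshold, 1122 higher and 894 lower with DO1, of which 58 and 76 changed at least 1.5-fold. The balance of directions depended on the choice of probe, with 1036 higher and 1044 lower for the mean of a gene's probes and 1703 higher and 1886 lower with every probe tested on its own. The clock genes Nr1d2, Dbp, Ciart and Per1 rose by 0.93 ± 0.10 (limma adjusted p = 2.01e-06), 0.76 ± 0.12, 0.74 ± 0.15 and 0.63 ± 0.14. The endothelial tight junction gene Cldn5 fell by 0.97 ± 0.10 (adjusted p = 2.49e-06). Rises were also found for the GTPase regulators Agap2 (1.31 ± 0.12), Rapgef5 (0.83 ± 0.11), Rasal2 (0.80 ± 0.09) and Arhgap35 (0.79 ± 0.10), and for the transcription factors Npas4 (0.81 ± 0.19) and Etv1 (0.80 ± 0.10). Falls were found for 2900060B14Rik by 1.19 ± 0.19, the dynein-dynactin genes Dctn1 by 1.03 ± 0.12 and Dynll2 by 0.97 ± 0.17, the RNA-binding Hnrnpa2b1 by 1.01 ± 0.13 and Ddx5 by 0.87 ± 0.12, the elongation factor Eef2 by 0.92 ± 0.12, the vesicle genes Syt11 by 0.94 ± 0.10 and Snap91 by 0.86 ± 0.11, and Smim10l1 by 0.91 ± 0.13. Agap2 and Etv1 had other probes that changed the opposite way, while 3 probes of Eef2 fell together. The second probes of Arhgap35, Hnrnpa2b1 and Snap91 did not pass, at −0.16 ± 0.09, −0.06 ± 0.10 and 0.21 ± 0.12. For the mean of a gene's probes Etv1 stood at 0.02 (adjusted p = 0.899) and Per1 at 0.30 (adjusted p = 0.0808).

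Some large log2 changes with DO1 in transgenic mice had wide errors. Fcer1g, an Fc receptor chain of myeloid cells, was higher by 2.80 ± 0.90 (limma adjusted p = 0.0468), Uap1 by 1.72 ± 0.49 (adjusted p = 0.0251) and Kbtbd11 by 0.99 ± 0.32 (adjusted p = 0.0499). Uap1 was at the lower of its 2 levels in 4 of 5 untreated and 1 of 6 treated transgenic mice. In the plot of single genes per mouse, Fcer1g stood near 6 in 4 of 5 untreated transgenic mice and at 5.99 in transgenic DO1 mouse 4, and between 10.2 and 10.9 in the other 5 DO1-treated mice. Transgenic untreated mouse 2 stood at 10.8, within the range of those 5. The Fcer1g difference thus rests on how many mice had low values, and no change among mice with high values was shown. These low values lie under the arrays' lower quartile of 6.18 and were not shown to be above background. Both the size of the Fcer1g difference and whether DO1 changed the gene are therefore uncertain. Leaving out any of 16 single samples raised the adjusted p of Fcer1g to between 0.0509 and 0.109 and that of Kbtbd11 to between 0.0519 and 0.115, and any of 6 raised that of Uap1 to between 0.0509 and 0.0723. For Uap1 these were transgenic DO1 mice 5 and 6 and transgenic untreated mice 1, 3, 4 and 5. For Fcer1g they were every sample except wild-type untreated mice 1 and 4, wild-type DO1 mice 1 and 5, transgenic DO1 mouse 4 and transgenic untreated mouse 2. For Kbtbd11 they were every sample except the 5 wild-type untreated mice and transgenic DO1 mouse 2.

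Of the gene lists, 4 passed in transgenic mice. Circadian clock genes were higher by 0.34 ± 0.07 (exact permutation test, adjusted p = 0.0267), with 6 of 14 risen and 0 fallen, and 7 higher when adjusted over the list alone. Deep-layer cortical neuron genes were higher by 0.17 ± 0.03, with 2 of 18 risen, Etv1 and Vat1l (0.40 ± 0.08), and 5 higher when adjusted over the list alone. Endothelial genes were lower by −0.16 ± 0.03 (adjusted p = 0.04), with 3 of 15 fallen, Cldn5, Egfl7 by 0.30 ± 0.06 and Bsg by 0.32 ± 0.09, the same number as when adjusted over the list alone. Without transgenic untreated mouse 5 the adjusted p of Bsg was 0.0523. The sex chromosome list was higher by 0.27 ± 0.05 through Xist (0.75 ± 0.16), against a median of 0.09 over its members' changes. A score made from the median of the list in each sample was lower by −0.04 instead. In each of the 4 lists all 6 treated samples lay beyond the mean of the untreated ones. Against all other genes with an estimated correlation the adjusted p was 0.291 for the clock, 0.228 for deep-layer neurons, 0.291 for endothelium and 0.738 for sex chromosome genes. The 4 lists lost the permutation call without any of the 6 transgenic DO1 mice. That loss says nothing about stability, since 5 against 5 samples allow no p under 0.00794, and 6 lists must reach it before any can pass. Without a transgenic untreated mouse the smallest p is 0.00476 and 4 lists must reach it. The endothelial list then lost the call without mouse 2, 3, 4 or 5, at adjusted p from 0.0503 to 0.0881, and the other 3 only without mouse 2, at 0.0587.

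The lists that were highest in untreated transgenic mice did not pass with DO1. Disease-associated microglia genes differed by −0.13 ± 0.10 (exact permutation test, adjusted p = 0.477), with 5 of 30 fallen and 0 risen, including Lyz2 by 0.58 ± 0.14, Clec7a by 0.43 ± 0.12, Hif1a by 0.39 ± 0.07 and Cd63 by 0.28 ± 0.06, and with 6 lower when adjusted over the list alone. Reactive astrocyte genes differed by −0.15 ± 0.11 (permutation adjusted p = 0.477), with Serpina3n, Vim and Timp1 fallen by 0.74 ± 0.20, 0.65 ± 0.17 and 0.55 ± 0.17. Lysosome genes differed by −0.13 ± 0.06 (permutation adjusted p = 0.356), with 2 of 24 risen, led by Lipa at 0.39 ± 0.07, and 4 fallen, or 4 higher and 7 lower when adjusted over the list alone. Complement genes differed by −0.15 ± 0.10, general microglia genes by −0.03 ± 0.09 and homeostatic microglia genes by 0.00 ± 0.10. The general microglia list holds Fcer1g, whose mean difference of 2.80 pulls its score upwards, and the score without Fcer1g was not tested. App, one of the transgene and promoter genes, was higher by 0.15 ± 0.04 (limma adjusted p = 0.0296) on the brightest of its 3 probes, and its other 2 probes differed by 0.06 ± 0.07 and −0.05 ± 0.07. Bace1, the beta-secretase gene, rose by 0.40 ± 0.08. Thy1 differed by 0.01 ± 0.07. Among general astrocyte genes Fgfr3 fell by 0.79 ± 0.05, Kcnj10 fell by 0.53 ± 0.13 and the water channel Aqp4 rose by 0.71 ± 0.13. With the mean of a gene's probes the calls ended for Etv1, for Egfl7 (adjusted p = 0.153), for Lyz2, Clec7a and Hif1a (adjusted p = 0.457, 0.354 and 0.32) and for App (adjusted p = 0.523). Several gene calls also ended without a single sample. They were Clec7a (transgenic untreated mouse 3 or 5, adjusted p up to 0.0611), Serpina3n and Vim (transgenic untreated mouse 2, 0.0589 and 0.0573), Timp1 (transgenic DO1 mouse 1, 2, 3, 5 or 6 or transgenic untreated mouse 2 or 3, up to 0.127) and App (transgenic DO1 mouse 2, 5 or 6 or transgenic untreated mouse 2 or 3, up to 0.0823). The other scores in transgenic mice that did not pass included excitatory neurons at 0.08 ± 0.03, synapse at 0.07 ± 0.02 and immediate early genes at 0.31 ± 0.13, with adjusted permutation p of 0.0641, 0.0801 and 0.27. Excitatory neuron genes passed without transgenic untreated mouse 5, synapse genes without mouse 4 and cholesterol synthesis genes (0.27 with all samples) without mouse 3, each at 0.044.

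The third comparison asks what DO1 changed in wild-type mice. Here 1695 features passed the threshold, 964 higher and 731 lower, of which 160 and 43 changed at least 1.5-fold. Without wild-type untreated mouse 4 the lower count was 457. Kbtbd11 was higher by 2.94 ± 0.32 (limma adjusted p = 3.73e-06) on its brighter probe, while its dimmer one differed by −0.07 ± 0.07. The brighter probe of Kbtbd11 stood at 6.69, 6.74 and 6.76 in wild-type untreated mice 1, 3 and 5, near the array median of 6.48, at 9.04 and 8.17 in mice 2 and 4, and between 9.98 and 10.9 in all 6 treated mice. With every probe tested on its own, 1537 were higher and 1514 lower. Rises of 1 or more on the log2 scale were also found for the non-coding RNA Xist (1.47 ± 0.16), the pseudogene Rnf170-ps (1.58 ± 0.36, with the same untreated mice 1, 3 and 5 at 7.19, 7.24 and 6.90 and the other 2 at 8.91 and 8.70), the chromatin genes Ankrd11 (1.24 ± 0.15) and Nipbl (1.15 ± 0.13), the imprinted Peg3 (1.20 ± 0.15), Agap2 (1.11 ± 0.12) and Rasal2 (1.07 ± 0.09). The next brightest probes of Ankrd11 and Nipbl did not follow, at 0.03 ± 0.07 and −0.05 ± 0.07, and that of Agap2 fell by 0.34 ± 0.07. The red cell genes Hba-a1 and Alas2 rose by 1.18 ± 0.28 and 1.07 ± 0.28. The near-identical chemokine genes Ccl21a and Ccl21c were lower, at −2.20 ± 0.70 (adjusted p = 0.0491) and −1.92 ± 0.60 (adjusted p = 0.0448), with the related LOC100041504 at −1.86 ± 0.58. Ccl21a lay at 2 separate levels across the mice, and its mean difference rests on wild-type DO1 mice 2, 4, 5 and 6, at 6.74 to 7.09. The other 2 treated mice stood at 9.15 and 9.93, within the untreated range that began at 9.11. In the same 4 mice Ccl21c was at 6.76 to 7.00 and LOC100041504 at 6.47 to 6.72, against 8.73 and 9.30 and 8.51 and 8.93 in the other 2. The low values of LOC100041504 lie near the array median of 6.48 and were not shown to be above background, so the size of its change is uncertain. The hypothalamic neuropeptide Avp fell by 1.09 ± 0.32. Falls near 0.9 were found for Ddx5 (by 0.96 ± 0.12), the ribonuclease Rnase1 (−0.90 ± 0.16), Smim10l1 (−0.88 ± 0.13), Snap91 (−0.84 ± 0.11), Hnrnpa2b1 (−0.82 ± 0.13) and Gm5814 (−0.80 ± 0.11). The second probe of Hnrnpa2b1 differed by 0.02 ± 0.10 and that of Snap91 by 0.36 ± 0.12, and for the mean of its probes Snap91 did not pass (limma adjusted p = 0.129). Leaving out any of 14 single samples raised the adjusted p of Ccl21a to between 0.0518 and 0.119, any of 10 that of Ccl21c to between 0.0501 and 0.114 and any of 12 that of LOC100041504 to between 0.0508 and 0.111. The Avp call ended without wild-type untreated mouse 3 or 4 or wild-type DO1 mouse 2, 4 or 6, at adjusted p from 0.0624 to 0.107. Ccl21a, Ccl21c and LOC100041504 each lost the call without any of wild-type untreated mice 1 to 4, wild-type DO1 mice 2, 4, 5 and 6 and transgenic untreated mice 1 and 4. Ccl21a and LOC100041504 lost it also without transgenic untreated mouse 2 or 3, and Ccl21a without transgenic untreated mouse 5 or transgenic DO1 mouse 5.

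In wild-type mice 6 lists passed, all higher with DO1 and each with every treated sample above every untreated one (exact permutation test, adjusted p = 0.0267 for sex chromosome genes and 0.016 for the others). Erythrocyte genes were higher by 0.69 ± 0.14, with 4 of 5 risen, including Hbb-b1 by 0.97 ± 0.30 and Slc4a1 by 0.32 ± 0.09. Deep-layer cortical neuron genes were higher by 0.18 ± 0.03, with Etv1, Drd1 and Nr4a2 risen by 0.67 ± 0.10, 0.38 ± 0.07 and 0.42 ± 0.13, and with 8 of 18 higher when adjusted over the list alone against 3 over all features. Etv1 rose on its brightest probe only, while its other 2 probes fell by 0.32 ± 0.10 and 0.50 ± 0.10 and the mean of its probes stood at −0.05 (limma adjusted p = 0.771). Excitatory cortical neuron genes were higher by 0.16 ± 0.03, with 5 of 12 risen, among them Grin2a by 0.41 ± 0.09 and Tbr1 by 0.32 ± 0.09, and 1 fallen, Slc17a6 by 0.34 ± 0.08. Synapse genes were higher by 0.16 ± 0.03, with 5 of 19 risen, including Cplx2 by 1.04 ± 0.15 and Syn2 by 0.78 ± 0.10, the latter with a second probe at −0.01 ± 0.08. The sex chromosome list was higher by 0.47 ± 0.08 through Xist, against a median of 0.03, and the transgene and promoter list by 0.12 ± 0.02, with App at 0.17 ± 0.04 (limma adjusted p = 0.0168) and Thy1 at 0.16 ± 0.07 (adjusted p = 0.186). With an estimated correlation the adjusted p was 0.395 for erythrocytes, 0.0622 for deep-layer neurons, 0.271 for excitatory neurons, 0.289 for synapse and 0.574 for the other 2 lists. Clock genes stood at 0.14 ± 0.05 (exact permutation test, adjusted p = 0.0686, but 0.042 without wild-type DO1 mouse 1), with Per1 and Dbp risen by 0.53 ± 0.14 and 0.43 ± 0.12. Disease-associated microglia genes stood at −0.06 ± 0.02 (permutation adjusted p = 0.116, but 0.042 without wild-type DO1 mouse 4), with 2 of 30 fallen. Cx3cr1 and Mef2c of the homeostatic microglia list rose by 0.90 ± 0.14 and 0.61 ± 0.12. Bace1 rose by 0.41 ± 0.08. The thalamus and hypothalamus list, which holds Avp, stood at −0.31 ± 0.13 (permutation adjusted p = 0.116).

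For the mean of a gene's probes the calls for App and Per1 in wild-type mice ended, at adjusted p of 0.147 and 0.0675. Several of the calls for list members ended without a single sample. For Per1 these were wild-type untreated mouse 3 or 4 (adjusted p up to 0.076), for Dbp wild-type DO1 mouse 2 or 5 or wild-type untreated mouse 4 or 5 (up to 0.0734), and for Tbr1 wild-type untreated mouse 5 (0.0722). For Slc4a1 they were wild-type untreated mouse 1 or 3 or wild-type DO1 mouse 2 or 6 (up to 0.0781), and for Nr4a2 wild-type untreated mouse 1 or 4 or wild-type DO1 mouse 1, 4, 5 or 6 (up to 0.122). Hbb-b1 lost the call without any of wild-type untreated mice 1, 2, 3 and 5, wild-type DO1 mice 1, 2, 4, 5 and 6, transgenic DO1 mice 5 and 6 and transgenic untreated mouse 2, at adjusted p up to 0.116.

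The DO1 effects in both genotypes, which share no samples, were then set against each other. Across the tested features, which are not independent replicates, their log2 changes correlated at r = 0.59, against a mean of 0.04 and a 95% range of −0.23 to 0.27 in 100 simulations of unchanged groups. There were 434 features higher and 369 lower with DO1 in both genotypes, where independent lists would share 60.3 and 36.4, and 3 were called in opposite directions. On the probe that stood for each gene, Agap2, Rasal2, Etv1, Xist, Kbtbd11, Stard4 (0.51 ± 0.09 in transgenic and 0.54 ± 0.09 in wild-type mice) and Lipa were among those higher in both, and Hnrnpa2b1, Ddx5, Snap91, Smim10l1 and the transporter Slc6a13 (−0.51 ± 0.09 and −0.43 ± 0.09) among those lower in both. Second probes followed the calls less closely for DO1 than for genotype. Among genes called in the DO1 effect with a second kept probe, 66.2% in transgenic and 69.7% in wild-type mice had a second probe that differed in the same direction, compared with 83.0% for the genotype effect in untreated mice.

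**Figure D2:**
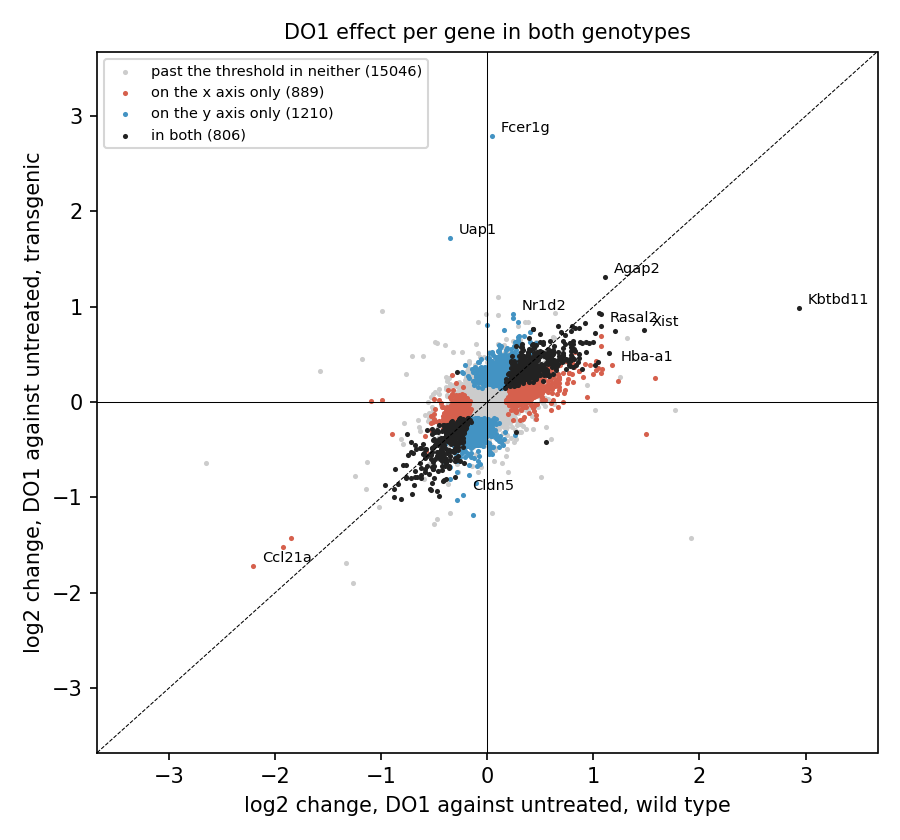
Log2 change with DO1 in wild-type mice (x axis) and in transgenic mice (y axis) for each of 17951 features; colours show in which comparison a feature passed limma's adjusted p of 0.05, and the dashed line marks equal changes. Most features called in both lay in the lower left or upper right quadrant, with 3 exceptions, while Fcer1g and Uap1 lay far from the dashed line but did not pass the test of the difference (limma adjusted p = 0.581 and 0.399).

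Whether DO1 moved the genes changed by the transgenes back was examined by relating the DO1 effect in transgenic mice to the genotype effect in untreated mice. Of the 1050 features higher in untreated transgenic mice, 161 were lower and 41 higher with DO1 in transgenic mice. Of the 902 features lower in untreated transgenic mice, 163 were higher and 33 lower with DO1. Independent lists would give 52.3 and 56.4 opposite calls, but both comparisons use the same untreated transgenic samples, which alone produces opposite changes. Across features r was −0.26, compared with a mean of −0.51 and a 95% range of −0.66 to −0.31 in simulations of unchanged groups. The covariance was −0.0106 against a simulated −0.00607, with a 95% range of −0.00904 to −0.00256. The covariance was thus more negative than its range. The r was less negative than its range, but r is scaled by the spread of the changes. Simulated groups hold no genotype or DO1 effect to widen that spread, so their range cannot be used to judge r. The covariance gives no count of features that moved back, and features with large changes weigh most in it. With the untreated transgenic samples divided between both comparisons, the mean r over 20 splits was −0.09, between −0.17 and −0.004. The mean covariance over these splits was −0.00417. The median genotype change of the higher features was 0.39 in untreated and 0.26 in DO1-treated mice, and that of the lower ones −0.29 and −0.12. Features picked for a large change in untreated mice tend to show a smaller one in other samples without any treatment effect.

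The difference of the DO1 effects between genotypes was tested directly. Only 9 of 17951 features passed, all with a lower DO1 effect in transgenic mice, and 1482 had an unadjusted p under 0.05. Of the 9, 6 were also called higher in untreated transgenic mice and lower with DO1 in transgenic mice. These tests all use the same untreated transgenic samples, so the overlap alone does not show that DO1 moved the features back. Mfhas1 differed by −0.89 ± 0.15 (limma adjusted p = 0.0166), with a rise of 0.94 in wild-type mice and a change of 0.05 in transgenic ones. Gsk3b, a kinase that phosphorylates tau, differed by −0.69 ± 0.13 (adjusted p = 0.0359), with changes of 0.60 in wild-type and −0.09 in transgenic mice. The actin regulator Wasf3 differed by −0.74 ± 0.11 and Fgfr3 by −0.48 ± 0.07 (adjusted p = 0.00767 for both), the calcium pump Atp2b3 by −0.60 ± 0.11 and Cxxc5 by −0.57 ± 0.10, and 3 further probes are unnamed here. For the mean of a gene's probes Fgfr3 and Atp2b3 did not pass (adjusted p = 0.0662 and 0.0779). The count fell to 5 without wild-type untreated mouse 1, transgenic DO1 mouse 3 or 5 or transgenic untreated mouse 4, to 4 without wild-type DO1 mouse 1 or transgenic DO1 mouse 6, and to 3 without transgenic untreated mouse 2. It rose to 15 without wild-type DO1 mouse 3, 16 without transgenic untreated mouse 1 and 19 without wild-type untreated mouse 5. Gsk3b, Cxxc5 and Atp2b3 lost the call without any of 15, 14 and 9 single samples, at adjusted p of up to 0.11, 0.0939 and 0.0783. For Gsk3b only wild-type untreated mice 3 and 5, wild-type DO1 mice 3 and 4, transgenic DO1 mice 1 and 2 and transgenic untreated mouse 1 could be left out without ending it. For Cxxc5 these were wild-type untreated mice 1, 2 and 5, wild-type DO1 mice 2 and 3, transgenic DO1 mice 1 and 4 and transgenic untreated mouse 1. The Atp2b3 call ended without wild-type untreated mouse 1 or 3, wild-type DO1 mouse 1, transgenic DO1 mouse 3, 5 or 6 or transgenic untreated mouse 2, 4 or 5. None of the 37 lists passed, and 3 had an unadjusted permutation p under 0.05, namely endothelium (−0.18 ± 0.05, p = 0.00875), thalamus and hypothalamus (0.49 ± 0.19, p = 0.0209), and heat shock and unfolded protein response (0.12 ± 0.05, p = 0.0313). Nr1d2 differed by 0.68 ± 0.14 (limma adjusted p = 0.0634) and Cldn5 by −0.75 ± 0.15 (adjusted p = 0.0536), so a different DO1 effect on either was not shown. Nr1d2 passed without transgenic DO1 mouse 1 (0.0393), transgenic untreated mouse 1 (0.0375) or wild-type untreated mouse 5 (0.0361). Cldn5 passed without any of these (0.045, 0.0399 and 0.0496), wild-type DO1 mouse 3 (0.0399) or transgenic untreated mouse 3 (0.00651).

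The last comparison asks what distinguished transgenic from wild-type mice when both received DO1. Of 898 features that passed, 668 were higher and 230 lower. The lower count depended on single samples. It was 132 and 139 without wild-type DO1 mouse 1 and 2, 119, 124 and 145 without transgenic DO1 mouse 4, 5 and 6, and 375 without transgenic DO1 mouse 2. The same kinds of genes led as in untreated mice, with Ccl4, again near the array median in wild-type mice as were Ccl3 and Cst7, higher by 3.19 ± 0.13 (limma adjusted p = 5.99e-14), Ccl3 by 3.00 ± 0.14, Cst7 by 2.93 ± 0.14, Lyz2 by 2.72 ± 0.13, Gfap by 2.67 ± 0.11, Lyz1 by 2.55 ± 0.16, Trem2 by 2.53 ± 0.17, Serpina3n by 2.53 ± 0.19, Tyrobp by 2.41 ± 0.15 and Cd68 by 2.21 ± 0.10. Thy1 was higher by 0.72 ± 0.07. Disease-associated microglia genes were higher by 1.22 ± 0.08 (exact permutation test, adjusted p = 0.00667), with 24 of 30 risen and 26 higher when adjusted over the list alone. Lists of general microglia (0.98 ± 0.06), complement (0.93 ± 0.08), reactive astrocytes (0.63 ± 0.09), lysosome (0.62 ± 0.06), homeostatic microglia (0.59 ± 0.10), cytokines and chemokines (0.34 ± 0.03), cholesterol synthesis (0.22 ± 0.03) and general astrocytes (0.18 ± 0.03) reached the same adjusted p and also passed with an estimated correlation, as did MHC class II genes at 0.61 ± 0.20 (permutation adjusted p = 0.015). In each of these 10 lists and in the endothelial one all 6 transgenic samples lay beyond the wild-type mean. Cholesterol synthesis genes with called rises included Fdps (0.44 ± 0.05), Mvd (0.47 ± 0.06) and Stard4 (0.52 ± 0.09), with 4 of 16 risen and 9 higher when adjusted over the list alone. Endothelial genes were lower by −0.16 ± 0.04 (permutation adjusted p = 0.0123, and 0.0236 with an estimated correlation), with 1 of 15 fallen, Itm2a by 0.53 ± 0.16. The Itm2a call ended without any of 15 single samples, at adjusted p up to 0.128, and held only without wild-type DO1 mouse 5, transgenic DO1 mouse 1, 2 or 6 or transgenic untreated mouse 1, 2 or 4. Antioxidant and Nrf2 target genes stood at 0.13 ± 0.05 (permutation adjusted p = 0.0521) and passed only with an estimated correlation, at 0.0236. MHC class I genes at 0.41 ± 0.18 and interferon response genes at 0.33 ± 0.17 did not pass (permutation adjusted p = 0.0582 and 0.122). Without transgenic DO1 mouse 5, which was highest in both, these scores were 0.27 and 0.21 (permutation adjusted p = 0.113 and 0.208). The class I list passed without wild-type DO1 mouse 6 (0.0379) or transgenic DO1 mouse 2 (0.0236), the interferon list without wild-type DO1 mouse 4 (0.0445), and the antioxidant list without transgenic DO1 mouse 2 (0.0337) or 3 (0.015).

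A further 8 lists passed the permutation test in DO1-treated mice but had an adjusted p above the threshold with an estimated correlation. Their exact permutation adjusted p was 0.00667 for striatum, housekeeping and transgene genes, 0.015 for amyloid processing and synapse, 0.0188 for oligodendrocytes, 0.0356 for thalamus and hypothalamus and 0.0379 for inhibitory neurons. All 6 transgenic samples lay beyond the wild-type mean in each of them except the thalamus and hypothalamus list, with 5 of 6. Oligodendrocyte and myelin genes were higher by 0.18 ± 0.05 (0.128 with an estimated correlation, as an adjusted p), with Trf risen by 0.51 ± 0.10 and Cldn11 by 0.37 ± 0.09. Amyloid processing genes were higher by 0.16 ± 0.04 (adjusted p = 0.0748 with an estimated correlation), with Apoe risen by 0.85 ± 0.08 and Mme fallen by 0.43 ± 0.08 on its brightest probe (limma adjusted p = 0.0531 for the mean of its probes). Thalamus and hypothalamus genes were higher by 0.35 ± 0.13 (adjusted p = 0.32 with an estimated correlation), with Avp at 1.17 ± 0.30 and Prkcd at 0.39 ± 0.10, and lost the call without wild-type DO1 mouse 2, 4, 5 or 6 or transgenic DO1 mouse 1, at adjusted p from 0.0506 to 0.0763. The Avp call ended without wild-type DO1 mouse 2, 4 or 6 or transgenic DO1 mouse 4 or 5, at adjusted p from 0.0577 to 0.0653. Lower lists were striatum at −0.16 ± 0.04, inhibitory neurons at −0.07 ± 0.02 and synapse at −0.07 ± 0.02 (adjusted p = 0.0842, 0.298 and 0.0762 with an estimated correlation), with Pvalb fallen by 0.27 ± 0.07 and Dlg4 by 0.30 ± 0.06. In the striatum list 0 of 12 passed over all features and 5 were lower when adjusted over the list alone. The inhibitory neuron list lost the permutation call without wild-type DO1 mouse 2, 4 or 5 or transgenic DO1 mouse 2, 4, 5 or 6, at adjusted p from 0.0582 to 0.0674, and Pvalb without wild-type DO1 mouse 2 or 4 or transgenic DO1 mouse 4 or 5, at up to 0.0729. Housekeeping genes at 0.14 ± 0.04 and transgene and promoter genes at 0.20 ± 0.02 moved through Gusb and Thy1 (adjusted p = 0.405 for both with an estimated correlation), and the median of the transgene list was −0.03. Clock genes stood at −0.06 ± 0.05 (exact permutation test, adjusted p = 0.336). Of the 10 largest falls, Abi3bp (by 0.72 ± 0.13), Cacng7 (by 0.63 ± 0.11) and Tsc22d1 (by 0.59 ± 0.14) led, followed by Dctn1, Itm2a, Syt11, Enox1, Psme2, Gabra3 and Atp2b3, which fell by 0.54, 0.53, 0.53, 0.51, 0.49, 0.49 and 0.48. For the mean of its probes Syt11 did not pass (adjusted p = 0.113). Gabra3 lost the call without wild-type untreated mouse 2, wild-type DO1 mouse 1, 2 or 3 or transgenic DO1 mouse 1, 3, 4, 5 or 6, at adjusted p up to 0.117.

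The genotype effects without and with DO1, which share no samples, correlated at r = 0.70 across features, against a mean of 0.04 and a 95% range of −0.15 to 0.34 in simulations of unchanged groups. There were 514 features higher and 73 lower in transgenic mice under both conditions, where independent lists would share 39.1 and 11.6, and 5 were called in opposite directions.

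**Figure D3:**
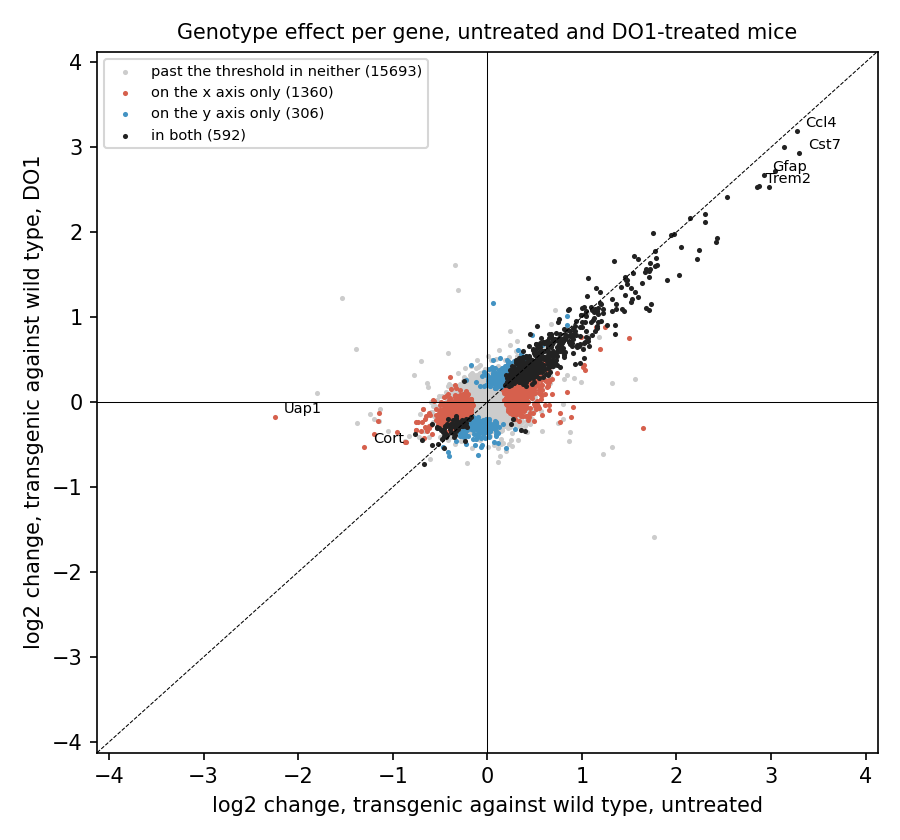
Log2 change in transgenic against wild-type mice without DO1 (x axis) and with DO1 (y axis) for each of 17951 features; colours show in which comparison a feature passed limma's adjusted p of 0.05, and the dashed line marks equal changes. The largest rises, such as Ccl4 at 3.27 and 3.19, lay near the dashed line, while Uap1, at the lower of 2 levels in 4 of 5 untreated transgenic mice, differed by −2.25 without and −0.17 with DO1. These 2 effects of Uap1 were not shown to differ (limma adjusted p = 0.399).

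**Figure D4:**
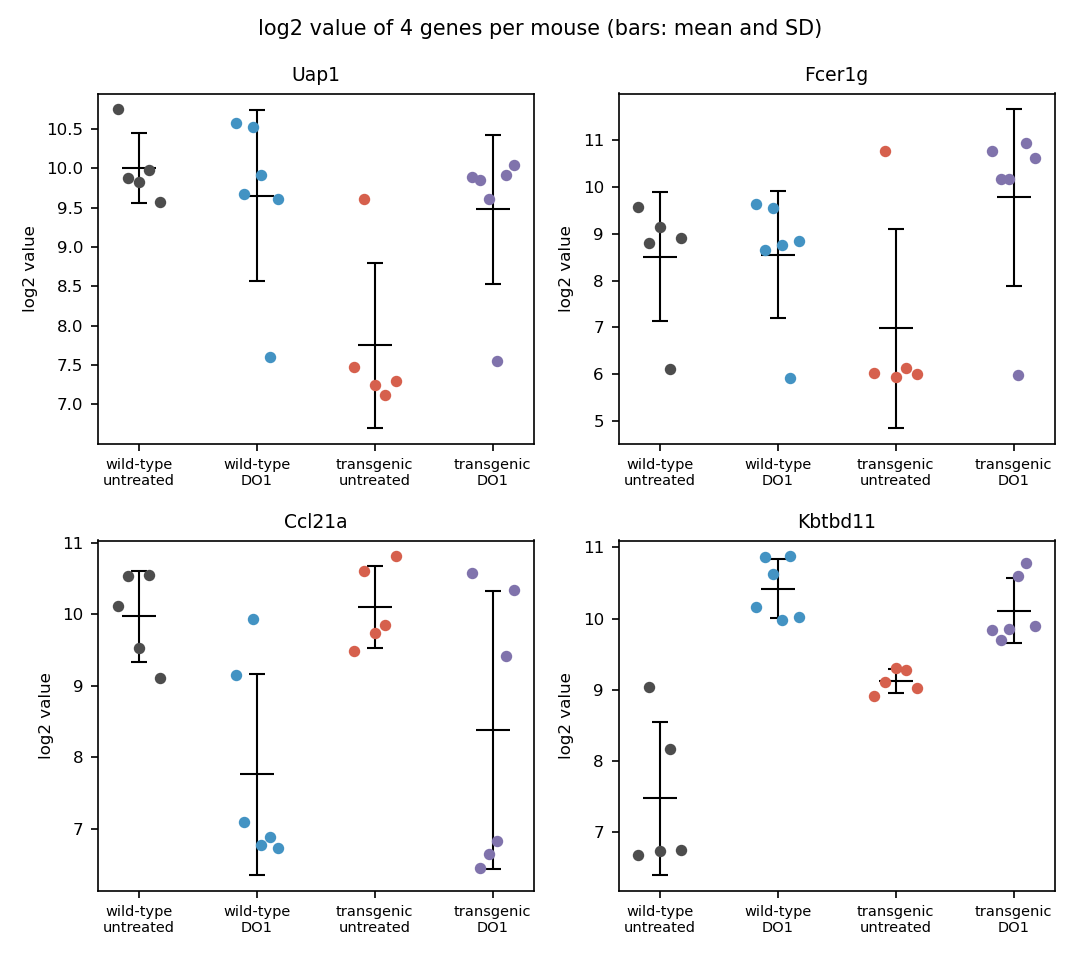
Log2 value of Uap1, Fcer1g, Ccl21a and Kbtbd11 in each mouse by group; points are samples, horizontal bars are means and vertical bars are SD, with n = 5, 6, 5 and 6. Fcer1g lay near 6 in some mice of every group, for example at 6.12 in wild-type untreated mouse 4 and 5.92 in wild-type DO1 mouse 5.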

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

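The tests of brightness-dependent normalization and of other cell types were chosen after the results were seen. The search for single samples far from their group covered the 37 list scores and the 65 genes with the largest rises or falls, in each of the 4 groups. It found 24 in 408 checks, or 5.88%, where chance gives about 5%, so their number alone is not unusual.

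Several concern Uap1 and Fcer1g. Uap1 was at 7.6 in wild-type DO1 mouse 5 (others 9.61 to 10.6), at 9.61 in transgenic untreated mouse 2 (others 7.12 to 7.48) and at 7.56 in transgenic DO1 mouse 4 (others 9.61 to 10.05). Fcer1g was at 6.12 in wild-type untreated mouse 4, 5.92 in wild-type DO1 mouse 5, 10.8 in transgenic untreated mouse 2 and 5.99 in transgenic DO1 mouse 4. Wild-type DO1 mouse 5 was also lowest for Hnrnpa2b1 (9.28), Snap91 (7.46) and Gm5814 (9.11). Other single values were Hnrnpa2b1 at 10.9 and Cst7 at 9.44 in transgenic untreated mouse 4, Rapgef5 at 9.69 in transgenic untreated mouse 2, Nipbl at 9.23 in transgenic untreated mouse 1 and Per2 at 10.1 in transgenic untreated mouse 3. In treated mice they were Gfap at 13.7 in transgenic DO1 mouse 3, Rnf170-ps at 7.24 in transgenic DO1 mouse 1, Ryr1 at 8.77 in wild-type DO1 mouse 2 and Ankrd11 at 9.81 in wild-type DO1 mouse 3. Among list scores, general microglia and macrophages stood at 8.76 in transgenic untreated mouse 2 (others 8.33 to 8.43), MHC class II genes at 8.69 in transgenic DO1 mouse 5 and immediate early genes at 9.56 in transgenic untreated mouse 3. The general microglia list holds Fcer1g, so its high score in transgenic untreated mouse 2 is in part the high value of Fcer1g there. Cytokines and chemokines stood at 7.52 in wild-type DO1 mouse 4, and deep-layer neurons at 9.59 in wild-type untreated mouse 2.

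A test of the difference between the DO1 effects in transgenic and wild-type mice was passed by 9 features. The differences were −0.74 for Wasf3, −0.48 for Fgfr3, −0.89 for Mfhas1, −0.60 for Atp2b3, −0.57 for Cxxc5 and −0.69 for Gsk3b, and −0.96, −0.52 and −0.54 for the unnamed probes ILMN_2514631, ILMN_1224842 and ILMN_2531554. Of 100 splits of the samples, 1 gave as many calls, the real one, and the highest other gave 6. These splits shuffled treatment within each genotype, which also breaks up the DO1 effect that both genotypes share and adds it to the spread. They therefore cannot tell whether chance alone would give 9 calls for a difference between genotypes, and the margin over the highest other is small. 

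The other counts were tested against splits of the samples of the groups compared. In the genotype effect in untreated mice, 1 of 100 splits, the real one, reached 1952, and the highest other gave 66. In the DO1 effect in transgenic mice the real 2016 stood against a highest other of 966, in the DO1 effect in wild-type mice 1695 against 664, and in the genotype effect in DO1-treated mice 898 against 299. No other split drawn reached the real count in any of these, so a chance division of the samples is an unlikely source of it.

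The 803 features called in the same direction with DO1 in both genotypes form the first pattern that was weighed. For a normalization error that depends on brightness, 95.77% of these calls (769 of 803) remained under cyclic loess. The mean change had a rank correlation of −0.0549 with intensity. The arrays already shared a distribution, which left these checks little room to find such an error, so they do not exclude it. Single probes that shift without their gene cannot be told apart from gene changes, because r between both probes' changes over 296 genes was 0.4444 (95% interval 0.348 to 0.532), between the bounds set beforehand of 0.2 and 0.5. A processing batch also stays open, since treated and untreated mice share 0 title numbers, each group has its own block of numbers and no batch is given. An effect of DO1, which the design names, remains an open explanation beside them.

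The second pattern is the 32 features with an absolute log2 change of at least 1 with DO1. Other cell types or regions as a source stay open, with 9.375% (3 of 32, Hba-a1, Alas2 and Avp) in the lists of erythrocytes, meninges, choroid plexus or other regions. The lists hold 68 of the tested features (0.379%), so 0.121 of 32 would be there by chance and the bounds set, including 10% as a share that argues against this source, had no means of deciding. For those 3 genes residual blood or differences in dissection remain possible, and the erythrocyte list was higher with Hba-a1 and Alas2. A strain variant under a probe, or a copy number variant, could not be decided for the set. By a criterion of a gap over 4 times the pooled spread, 6.25% (2 of 32, Uap1 and Ccl21a) lay at 2 separate levels. Others missed that criterion but were also split. Ccl21c stood at 6.76 to 7.00 in some mice and at 8.72 or more in the others. LOC100041504 stood at 6.46 to 6.72 or at 8.32 or more. The low count therefore does not weigh against such a variant. The median ratio of the second probe's change to the first's was 0.117 over the 12 genes with a second probe, which is low.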

How the results depend on the processing

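No alternative was added after the data were examined. No paired analysis was possible because replicate numbers follow accession order and pair no samples. Subtracting the 75th percentile and quantile normalization changed nothing, as the arrays already share a distribution, and so say nothing about stability. The first residual component is balanced over the groups by construction and cannot change a log2 difference, only the spread around it. The calls that it adds say nothing about stability either. With every probe tested on its own, 3589 probes passed for DO1 in transgenic mice, 3051 for DO1 in wild-type mice and 16 for the difference of the DO1 effects, where more features enter by construction. The count for that difference rose to 15 with trended and robust moderation and 20 with the first residual component. Without a single sample it was 5 (wild-type untreated 1), 4 (wild-type DO1 1), 15 (wild-type DO1 3), 5 (transgenic DO1 3), 5 (transgenic DO1 5), 4 (transgenic DO1 6), 16 (transgenic untreated 1), 3 (transgenic untreated 2), 5 (transgenic untreated 4) and 19 (wild-type untreated 5). The other total counts stayed within 1.5 times the reported ones, with left-out ranges of 1426 to 2112 for genotype in untreated mice, 1481 to 2139 and 1141 to 1785 for DO1 in transgenic and wild-type mice, and 632 to 1148 for genotype in DO1-treated mice. The calls themselves changed more than these totals. The share of reported calls kept in the same direction fell to 67.2% for genotype in untreated mice, with only the compared groups. For DO1 it fell to 67.4% in transgenic mice (without transgenic untreated 4) and 66.0% in wild-type mice (without wild-type untreated 4). For genotype in DO1-treated mice it fell to 69.3% (without transgenic DO1 4 or 5). The counts of lower calls alone moved further than the totals. Lower calls numbered 552 against 902 with only the compared groups for genotype in untreated mice, and 414 against 230 with the first residual component and 374 with every probe on its own for genotype in DO1-treated mice. Without a single sample they ranged from 119 to 375 in the latter, and fell to 590 (transgenic untreated 2) for genotype in untreated mice and 457 (wild-type untreated 4) for DO1 in wild-type mice. Cyclic loess moved the share of higher calls by at most 9.34 percentage points, from 53.8% to 63.1% for genotype in untreated mice. With every probe tested on its own the share fell from 55.7% to 47.5% for DO1 in transgenic mice and from 56.9% to 50.4% for DO1 in wild-type mice. The relation of the DO1 effect to the genotype effect was −0.0897 with split controls and −0.157 over the features called in DO1-treated mice (left-out range −0.323 to −0.199). Without the filter on dim probes the relation of the genotype effects was 0.6515 (left-out range 0.645 to 0.705) and that of the DO1 effects 0.5401 (0.555 to 0.603). Of 13823 recomputed values of named genes 12967 kept their side of the threshold, 786 lost and 67 gained a call and 3 reversed, all with the mean of a gene's probes: 0.006732 for Dgkh, DO1 effect in transgenic mice, −0.0496 for Etv1, DO1 effect in wild-type mice, and −0.005281 for Ctsa, DO1 effect in wild-type mice. That total includes 408 values each for the 75th percentile, quantile normalization and the first residual component, which say nothing about stability. It also includes samples left out of groups outside a comparison, which cannot move its log2 changes, so the share kept overstates stability. Of 5180 list values 4997 kept their side, 129 lost and 51 gained a call and 3 reversed when the score was the median of a list in each sample, which is not the median of its members' changes: sex chromosome genes at −0.0254 for genotype in untreated mice and −0.0400 for DO1 in transgenic mice, and housekeeping genes at −0.0108 for genotype in DO1-treated mice. The cause of these changes was not tested, unless stated. With detection values not used, signal over background limits what can be said of dim probes.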

Other observations

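The tests of lower neuronal activity and of neighbouring genes without interferon-induced GTPases were chosen after the results were seen. The reading of the clock gene test was also changed after its value was known, as described with it.

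Some genes of single pathways moved apart with DO1 in transgenic mice. Of the oxidative phosphorylation genes, Cox7a2 and Atp5a1 rose by 0.47 ± 0.10 and 0.44 ± 0.10, and Sdhc and Cox5b fell by 0.32 ± 0.09 and 0.19 ± 0.06, with a list score of 0.04 ± 0.02 that did not pass. Of the heat shock and unfolded protein response genes, the chaperone Hsp90aa1 rose by 0.69 ± 0.11 and Dnajb9 by 0.41 ± 0.10, while Hspa1b, chosen after its values were seen, fell by 0.29 ± 0.06. Of the synapse genes, Dlg4 fell by 0.55 ± 0.06 and Syn2 rose by 0.43 ± 0.10. Of the glucocorticoid targets, Tsc22d3, Hif3a and Ddit4 rose by 0.48 ± 0.09, 0.42 ± 0.10 and 0.27 ± 0.08, and the list score was 0.09 ± 0.07. In the cholesterol synthesis list, Stard4, Sc5d and Dhcr7 rose by 0.51 ± 0.09, 0.34 ± 0.09 and 0.29 ± 0.08, and Nsdhl fell by 0.38 ± 0.11. Without transgenic untreated mouse 5 the adjusted p was 0.0573 for Nsdhl and at most 0.074 for Sc5d, which also lost its call without transgenic untreated mouse 2. Without transgenic untreated mouse 4 it was 0.0698 for Sdhc and at most 0.0947 for Cox5b, which also lost its call without transgenic DO1 mouse 3 or 6. Ddit4 lost its call without any of transgenic DO1 mice 4, 5 and 6 and transgenic untreated mice 2, 3 and 5, at adjusted p from 0.0639 to 0.0858. For the mean of a gene's probes the calls for Hsp90aa1, Syn2 and Tsc22d3 ended, with log2 changes of 0.16, 0.16 and 0.25 (limma adjusted p = 0.0686, 0.149 and 0.0607).

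The clock genes, lower in untreated transgenic mice than in the other groups, form the third pattern that was weighed. If the untreated transgenic mice had been killed at another time of day, genes of the phase of Arntl would move opposite to those of the phase of Per. The 8 Per-phase genes differed by −0.296 (exact permutation p = 0.00794) and the 3 Arntl-phase genes by −0.170 (exact permutation p = 0.151), and the exact permutation p of the difference was 0.4206. The rule written beforehand counted either of these against this explanation: a p of 0.05 or more, or Arntl-phase genes that move the same way. Both were met, so the prediction failed by that rule. The reading was changed to undecided only after the values were seen, since the change of the 3 Arntl-phase genes did not pass and its direction is uncertain. A time-of-day difference is thus not excluded, and this test gives no evidence for it. Lower neuronal activity may also be involved, since the immediate early gene score was lower by −0.431 in untreated transgenic mice than in all others (exact permutation p = 0.002354 over 26334 splits), but the score had been seen beforehand, and low activity at killing and a lasting deficit would look alike.

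A number of genes lay at 2 separate levels across the mice, 40 named and 5 unnamed, by a criterion of a gap over 4 times the pooled spread. The hypothesis was that the mixed background leaves strain segments that differ between mice, so that neighbouring genes would switch together. Among the 40 named genes, 2 pairs lay within 10 tested genes of each other and had values that correlated over mice. The criterion was an r of at least 0.7 in size with group means removed. In 1000 random placements the mean count was 0.019 and the highest 1 (permutation p of the placements = 0.000999, the smallest they can give). The 2 pairs, chosen for their values, were Ccl21a with Rusc2, and Igtp with Irgm2. The latter encode interferon-induced GTPases, and both were high in wild-type DO1 mouse 6 (9.31 and 9.48) and transgenic DO1 mouse 5 (9.61 and 9.36), as was Gbp3 (10.1 and 10.2), so an interferon response in these mice could equally give that pair. Without such genes 1 pair remained (permutation p of the placements = 0.018), so the result in favour of strain segments may rest on Ccl21a and Rusc2 alone. That pair lay at the limit of 10 genes apart, and its low mice matched only in part. Wild-type DO1 mice 2 and 6 were low for Ccl21a (7.09 and 6.74) but not for Rusc2 (11.05 and 10.94). Uap1 and Fcer1g were 16 tested genes apart, outside the limit, with r = 0.892 over mice, and are therefore not counted, and Fcer1g did not meet the criterion of 2 levels. Segments shared by littermates within a group would appear as a treatment or genotype effect, which was not tested.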
